A study of Homo sapiens with 15 samples.

How the data were processed

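RNA was measured in 15 posterior fossa ependymomas, tumours of the ependymal lineage in the hindbrain. Per the labels' protocols, RNA was isolated with Trizol and treated with DNase, libraries followed the Illumina TruSeq protocol, and sequencing used an Illumina HiSeq instrument. The groups are those of the labels: 11 tumours with low global H3K27me3, the histone mark deposited by Polycomb repressive complex PRC2, and 4 tumours with high global H3K27me3. Replicate numbers are the tumour numbers of the labels. The labels do not state more about whether tumours are independent, so p-values measure the spread between these 15 samples.

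The authors deposited raw read counts per gene, with no normalization, for 53986 versioned Ensembl gene identifiers in 15 columns. Per the submitters' processing notes, STAR 2.3, SAMtools and featureCounts were used with build GRCh37; their roles, settings, strand option and annotation are not given in the sources used here. The table holds 34 genes that GENCODE 29 places on unplaced or alternative scaffolds of a later build, so the annotation used for counting is unsettled and no coordinates are printed. GENCODE 29 supplied gene names, types and chromosome for 48922 identifiers. The other 5064 identifiers had no symbol and held between 0.0916% and 1.98% of the counts of a library. No 2 columns held identical values. Y-linked genes, XIST and TSIX, 478 identifiers in all, were removed before any test because these are human samples.

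From the deposited counts, differential expression was tested with edgeR 4.0.16 (R 4.3.3): filterByExpr by group, TMM size factors, estimated dispersions, and the quasi-likelihood F test of low against high tumours, with no covariate. Adjusted p-values are Benjamini-Hochberg values over the genes tested, and a gene was called at an adjusted p under 0.05. Log2 fold changes are low over high, given with the standard error implied by the F statistic. CPM values use TMM-scaled library sizes. Levels are means ± SD over 11 low or 4 high tumours. For genes with 1 to 3 reads over all 4 high libraries, the fitted fold depends on a prior count, so the depth-scaled ratio of summed reads is given with an exact 95% interval that covers counting error only.

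A set of 35 gene lists was fixed, together with the tests, the alternatives and the rule for named genes, before the data were examined. Each list with at least 4 tested members was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Each list score is the mean over members of log2 CPM standardised over the 15 tumours, and its difference between groups was tested with a two-sided exact permutation test over all ways to choose 4 of 15 tumours, for which the smallest possible p is 0.000733. Both sets of p-values were adjusted over 34 lists; cancer-testis antigens had 2 tested members and were not tested as a list. Members were also "adjusted over the list alone". Named genes are the 12 with the largest fold in each direction among called genes with a mean of at least 1 CPM, all 4 high tumours on one side of the low median and at least 9 of the 11 low tumours on the other side of the high median. Also, all PRC2 list members, LAMA2, TNC, NELL2, FOXJ1, VEGFA, KDM6A, KDM6B, DNMT1, DNMT3A and DNMT3B are named whatever their values. In addition, up to 2 higher and 2 lower called members of each list are named, or the 2 members with the smallest p where none was called. Locus names and immune receptor segments were left out. Any other gene in the text was chosen after its values were seen.

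The alternatives were RLE, upper-quartile or no size factors, no filter or a filter of at least 1 CPM in 4 tumours, each of the 15 tumours left out, DESeq2 1.42.0, limma-voom with and without sample weights, and 1 surrogate variable (sva 3.50.0). For single results, an adjusted p under 0.01, protein-coding genes alone, a test against a fold of 1.2, an estimated inter-gene correlation, fry, median scores and members of at least 1 CPM were also tried. Further alternatives chosen after seeing the data are named as such. Annotated transcript length and GC content came from the longest GENCODE 29 transcript. Figures were drawn with matplotlib 3.10.9.

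The procedure was tested on simulated counts drawn from the real means, dispersions and library sizes of the low against high comparison, with 200 of 16324 genes changed one by one. A list of 40 further genes was changed by a smaller fold and passed both list tests (camera adjusted p = 1.55e-34, exact permutation adjusted p = 0.0227). Of 30 unchanged lists, 0 passed either test. At an adjusted p under 0.05, edgeR recovered 41.0% of genes changed by 2 log2 units and 88.0% of genes changed by 3, and 3.65% of its calls were false. In the same simulation 24.4% of the calls of DESeq2 and 5.07% of those of limma-voom were false. The simulated genes varied independently, with no shift in library composition and no outlying tumour, and only better expressed genes were changed. These rates therefore need not hold for the real counts.

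Counts per library summed to between 6020520 and 43050300. With a biological coefficient of variation of 0.720 and 4 tumours in the smaller group, differences of 4-fold are often missed. In the simulation 41.0% of genes changed by 2 log2 units were recovered, and single-gene recovery was not scored for smaller folds.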

Results

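RNA-seq read counts were compared between 11 posterior fossa ependymomas with low global H3K27me3 and 4 with high global H3K27me3. H3K27me3 is a repressive mark on histone H3 that PRC2 deposits. Library totals ran from 6225010 to 43050300 reads in the low group and from 6020520 to 14641700 in the high group. TMM size factors were 1.06 ± 0.104 (SD, n = 11) in the low and 0.871 ± 0.0832 (SD, n = 4) in the high group (exact permutation p = 0.00659, adjusted p = 0.0659 over 10 library measures). Expression correlated between tumours, with a mean Spearman correlation to the other 14 of 0.763 to 0.868 in 14 tumours. H3K27me3-high replicate 17 had 0.691, the lowest value, and lay apart on the first principal component, which held 34.9% of the variance among the 1000 most variable genes. H3K27me3-low replicates 1 and 5 and H3K27me3-high replicate 18 stood apart in another way, with 31191, 31895 and 22865 genes expected at 5000000 reads against 18662 to 20119 in the other libraries.

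The composition of the libraries also differed, in 3 of the 4 high tumours. Cytosolic ribosomal protein genes took 5.37% to 5.68% of the counts in H3K27me3-high replicates 15, 16 and 18, against 0.464% to 2.91% in the low tumours and 0.576% in H3K27me3-high replicate 17. Replication-dependent histone genes took 1.64% to 5.53% in those 3 high tumours, against 0.169% to 1.35% in the low tumours and 0.194% in replicate 17. By exact two-sided permutation, the group difference had p = 0.0505 for the ribosomal protein share (adjusted p = 0.126) and p = 0.0432 for the histone share (adjusted p = 0.126). Sense-intronic transcripts took 0.642% to 1.90% of the counts in the same 3 high tumours and 0.0426% to 0.265% in the low tumours (exact permutation p = 0.0864, adjusted p = 0.144).

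The design asks which genes separate tumours with low H3K27me3 from those with high H3K27me3. ANGPTL1, a secreted angiopoietin-like protein, was among the genes most clearly higher in the low tumours, at 320 ± 180 CPM (SD, n = 11) against 7.94 ± 7.70 CPM (SD, n = 4). The groups did not overlap. EZHIP, a germline protein that binds and inhibits PRC2 and is listed under its older symbol CXorf67, was higher in every low tumour than in any high tumour. LAMA2, a basement membrane laminin chain used as a marker of one posterior fossa subgroup, was higher in the low group as well. The PRC2 core subunits EZH2, SUZ12 and EED were lower in the low group. These subunits and LAMA2 each lost their calls when H3K27me3-high replicate 15, 16 or 18 was left out. In all, edgeR's quasi-likelihood test called 866 of 16647 genes, 157 higher and 709 lower in low tumours, so 81.9% of the calls were lower.

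Of the called genes, 844 differed by at least 2-fold, 156 higher and 688 lower. Protein-coding genes made up 767 of the 866 calls. In 171 genes the groups did not overlap, 95 with all low tumours above and 76 with all low tumours below; this is 1.03% of genes, where chance gives 0.147%. The median log2 fold change over all genes was -0.01, and it was 0.25 with library totals as the only scaling, under which 168 genes were higher and 249 lower (59.7% lower). The counts rested on single high tumours: without H3K27me3-high replicate 17 there were 885 higher and 1978 lower genes, and without replicates 15, 16 or 18 there were 82 and 440, 48 and 255, or 33 and 100. Without H3K27me3-low replicates 1 and 5 and H3K27me3-high replicate 18, left out after seeing the data, the same test called 3 higher and 1 lower gene (2408 at an unadjusted p under 0.05), and without those 3 and replicate 17 it called 273 and 825. With log2 ribosomal protein share as a term, also chosen after seeing the data, it called 62 and 181.

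Among the 12 genes with the largest folds higher in low tumours under the naming rule, ANGPTL1 (ENSG00000116194.12) had a log2 fold change of 5.32 ± 0.73 (SE, edgeR adjusted p = 0.00268). DSC3, a desmosomal cadherin, reached 12.6 ± 9.79 CPM in low tumours against 0.136 ± 0.168 CPM in high tumours, a log2 fold change of 6.29 ± 1.16 (adjusted p = 0.00832). PLN, which encodes the calcium pump inhibitor phospholamban, stood at 71.5 ± 86.0 against 0.269 ± 0.252 CPM (log2 8.23 ± 1.74, adjusted p = 0.0153). BMP5, a secreted growth factor of the BMP family, stood at 90.4 ± 71.2 against 0.498 ± 0.388 CPM (log2 7.37 ± 1.68, adjusted p = 0.0209). MOXD1, a monooxygenase-like protein, and SCNN1B, a subunit of the epithelial sodium channel, had log2 fold changes of 6.69 ± 1.41 and 5.76 ± 1.43 (adjusted p = 0.0153 and 0.0301).

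DSC3, PLN, SCNN1B, MOXD1 and BMP5 had 5, 6, 7, 15 and 18 reads over the 4 high libraries, so the size of their fitted folds is uncertain. For the remaining 6 of these genes the high libraries held only 1 to 3 reads. NRK, a kinase gene, had 767 reads in the low libraries and 2 in the high ones, a depth-scaled ratio of 73.7 (exact 95% interval 20.3 to 609.7). The receptor gene NPY2R had 298 reads against 1, a ratio of 57.3 (10.2 to 2270). The pseudogene TAAR3P had 799 against 3, a ratio of 51.2 (17.5 to 249). The non-coding LINC00606 and LINC01697 had ratios of 65.7 (11.7 to 2604) and 109 (19.5 to 4311), from 1 read each in the high libraries. Summed reads give most weight to deep libraries such as H3K27me3-low replicates 1 and 2, and the intervals leave out the spread between tumours. LINC00606 stood at 5.85 and 4.44 CPM in H3K27me3-low replicates 1 and 5, against 0.139 to 1.54 CPM in the other low tumours. LGALS9C, a galectin gene with near-identical copies that can share reads, had a ratio of 68.6 (12.2 to 2717) and is uncertain. Among these 12 genes ANGPTL1, NRK and DSC3 kept their calls with each of the 15 tumours left out in turn. Leaving out H3K27me3-high replicate 18 ended the calls of the other 9, with adjusted p up to 0.151, replicates 15 and 16 ended some of them, replicate 17 ended those of LINC01697 and LGALS9C (adjusted p = 0.0511 and 0.0561), and LINC00606, LINC01697 and LGALS9C also lost theirs without some low tumours.

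The naming rule left 261 of the 709 lower genes eligible. Some larger folds, such as those of CRIP1 (log2 -6.82) and CCDC60 (log2 -5.30), fell outside it. Among the 12 eligible genes with the largest folds lower in low tumours, CSRNP2, a nuclear protein gene, stood at 27.7 ± 7.36 CPM against 265 ± 319 CPM in high tumours (log2 -3.26 ± 0.46, edgeR adjusted p = 0.0027), with no overlap between groups. Without H3K27me3-high replicate 18, which stood at 733 CPM, its log2 fold change was -1.98 (adjusted p = 0.0259). ADAMTS17, a secreted metalloprotease, stood at 28.9 ± 23.5 against 259 ± 211 CPM (log2 -3.17 ± 0.60, adjusted p = 0.00849). MDGA2, an adhesion molecule of neurons, stood at 4.08 ± 3.18 against 67.3 ± 50.1 CPM (log2 -4.04 ± 0.79, adjusted p = 0.0106). PABPC5 and its antisense partner PABPC5-AS1 had log2 fold changes of -4.38 ± 0.89 and -5.13 ± 1.03; the strand setting of the counting is not stated, so their reads cannot be told apart. VN1R1 and MIR181A2HG had log2 fold changes of -3.08 ± 0.50 and -3.31 ± 0.59. MIA, a secreted protein, had the largest fold, with 0.923 ± 1.10 against 281 ± 555 CPM. Without H3K27me3-high replicate 16 its log2 fold change was -1.78 (adjusted p = 0.399). GNG3, a G protein subunit, was carried by H3K27me3-high replicate 17, without which its log2 fold change was -0.53 (adjusted p = 0.725). SLITRK4, MIR4697HG and CDH8 had log2 fold changes of -4.04 ± 1.03, -3.05 ± 0.81 and -3.36 ± 0.95. They likewise lost their calls without replicate 17, where the folds were -1.86, -0.92 and -1.57 (adjusted p = 0.231, 0.469 and 0.289). In all, these calls were lost in 5, 10 and 13 of the 15 fits that left out a tumour. VN1R1, MIR181A2HG and ADAMTS17 lost theirs without replicate 18, with log2 fold changes of -1.44, -2.62 and -2.50 (adjusted p = 0.0680, 0.0628 and 0.0674). PABPC5-AS1 lost its call without replicate 16 (adjusted p = 0.0799).

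Of the 13 genes of the list of PRC2 subunits and EZHIP, 1 was higher and 4 were lower in low tumours over all genes, and 2 were higher and 4 lower adjusted over the list alone. EZHIP (CXorf67, ENSG00000187690.3) stood at 10.7 ± 6.92 CPM in low tumours against 0.592 ± 0.692 CPM in high tumours, a log2 fold change of 4.15 ± 0.90 (edgeR adjusted p = 0.0174). The methyltransferase EZH2 stood at 28.3 ± 11.9 against 75.6 ± 40.5 CPM (log2 -1.42 ± 0.39, adjusted p = 0.0460). Its partner SUZ12 stood at 115 ± 35.2 against 310 ± 188 CPM (log2 -1.43 ± 0.36, adjusted p = 0.0313), and EED at 20.9 ± 6.09 against 51.2 ± 26.0 CPM (log2 -1.29 ± 0.34, adjusted p = 0.0394). AEBP2, an accessory subunit, stood at 51.5 ± 19.6 against 256 ± 178 CPM (log2 -2.32 ± 0.42, adjusted p = 0.00809). H3K27me3-high replicate 17 had EZH2 at 17.1 CPM and EED at 12.3 CPM, below the low means, and so did not share the higher levels of the other 3 high tumours. EPOP, EZH1, PHF19, RBBP7, MTF2, RBBP4, PHF1 and JARID2 were not called, with log2 fold changes of 2.51, -0.48, -0.58, 0.35, -0.24, 0.15, 0.15 and 0.17. As a list the PRC2 genes did not pass (camera adjusted p = 0.612; exact permutation p = 0.123, adjusted p = 0.442). Its median of -0.24 turned to 0.04 with library totals as the only scaling, as did the sign for the oligodendrocyte (-0.08), Hedgehog (-0.23) and cell cycle inhibitor (-0.10) lists. Without replicate 17 the PRC2 median was -0.02 and the oligodendrocyte median 1.39. EZHIP lost its call without replicate 18 (adjusted p = 0.0680). EZH2 was close to the threshold and lost its call in 13 of the 15 fits that left out a tumour, SUZ12 in 4 and EED in 8, while AEBP2 kept its call in all 15. Without the 3 libraries that detect more genes, left out after seeing the data, all 5 calls were lost: EZHIP 3.84 (adjusted p = 0.135), AEBP2 -2.16 (0.116), EZH2 -1.14 (0.260), SUZ12 -0.99 (0.279) and EED -1.14 (0.243). Without replicate 17 as well, all 5 were called: EZHIP 4.82 (0.0421), AEBP2 -2.68 (0.00544), EZH2 -1.59 (0.0277), SUZ12 -1.40 (0.0345) and EED -1.58 (0.0216). With those 3 as a term, EZH2, SUZ12 and EED lost their calls (adjusted p = 0.0659, 0.0615 and 0.0607).

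**Figure D1:**
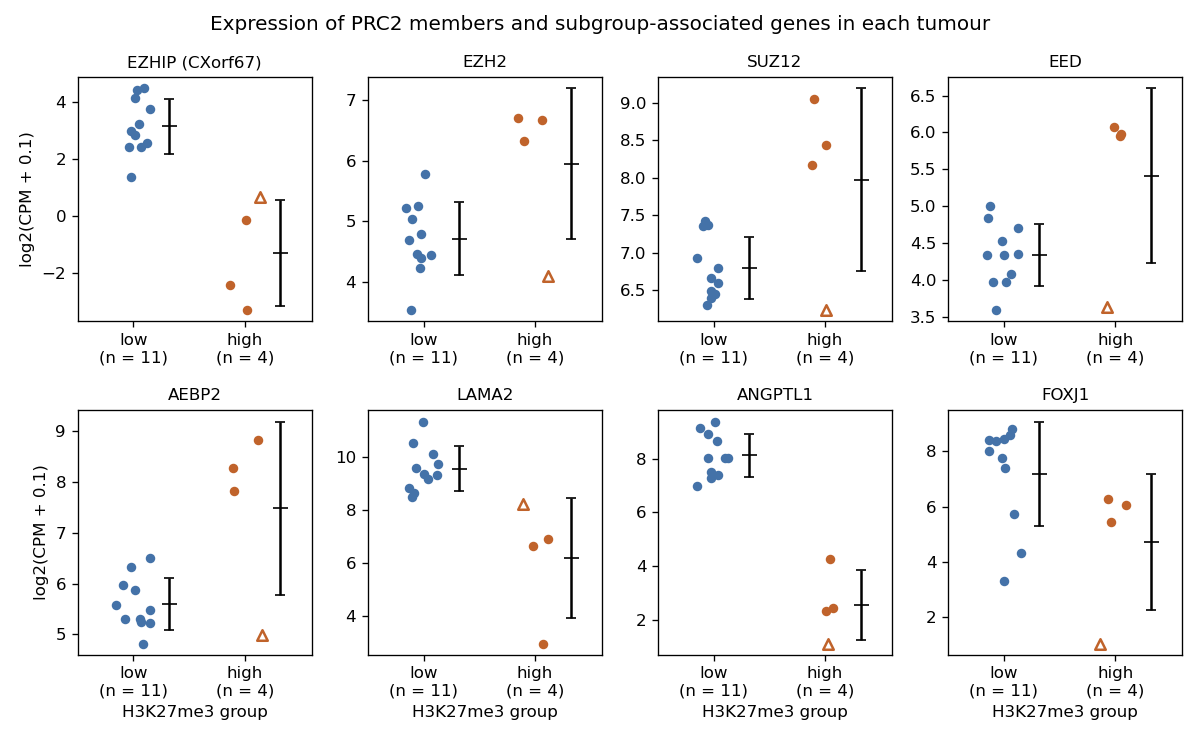
Expression per tumour as log2(CPM + 0.1) of EZHIP, EZH2, SUZ12, EED, AEBP2, LAMA2, ANGPTL1 and FOXJ1 in H3K27me3-low (blue, n = 11) and H3K27me3-high tumours (orange, n = 4); points are tumours, the open triangle is H3K27me3-high replicate 17, and bars are the mean and SD of the plotted values. EZHIP, LAMA2 and ANGPTL1 did not overlap between the groups, and replicate 17 lay with the low tumours for EZH2, SUZ12, EED and AEBP2.

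The subgroup marker LAMA2 stood at 894 ± 649 CPM in low tumours against 131 ± 122 CPM in high tumours (log2 2.77 ± 0.77, edgeR adjusted p = 0.0469), and its call was lost in 11 of the 15 fits that left out a tumour (adjusted p up to 0.146). TNC, an extracellular glycoprotein used as a marker of the same subgroup, stood at 3459 ± 3619 against 990.6 ± 1318 CPM and was not called (adjusted p = 0.425). NELL2, a neuronal secreted protein used as a marker of the other subgroup, stood at 144 ± 133 against 210 ± 144 CPM (adjusted p = 0.781). The angiogenic factor VEGFA stood at 119 ± 168 against 24.95 ± 28.05 CPM (adjusted p = 0.263). Among the 18 PRC1 subunits and H3K27 demethylases, PCGF6 was lower (log2 -1.67 ± 0.44, adjusted p = 0.0366), while the demethylases KDM6A and KDM6B had log2 fold changes of -0.28 ± 0.33 and 0.31 ± 0.46. Among 16 genes of the DNA methylation machinery, UHRF2 was lower (log2 -1.07 ± 0.30, adjusted p = 0.0489), with 2 lower adjusted over the list alone. The methyltransferases DNMT1, DNMT3A and DNMT3B had log2 fold changes of -0.33, 0.55 and -1.18 and were not called. The list median of the DNA methylation machinery was -0.04 and turned to 0.19 with library totals as the only scaling and to 0.44 without replicate 17. PCGF6 and UHRF2 lost their calls without replicate 18 (adjusted p = 0.227 and 0.151) and without several other tumours.

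Of 78 cytosolic ribosomal protein genes, 22 were lower and 0 higher in low tumours, with 57 lower adjusted over the list alone and a median log2 fold change of -1.58. RPS29 stood at 21.8 ± 16.1 against 190 ± 197 CPM (log2 -3.12 ± 0.64, edgeR adjusted p = 0.0131). RPL37A stood at 30.2 ± 12.8 against 112 ± 67.1 CPM (log2 -1.89 ± 0.41, adjusted p = 0.0185). Of 63 replication-dependent histone genes, 25 were lower and 0 higher, with 48 lower adjusted over the list alone and a median of -1.93; HIST1H4K and HIST1H2AK had log2 fold changes of -4.77 ± 0.84 and -4.33 ± 0.83. Both lists were lower by camera (adjusted p = 9.06e-20 and 5.37e-18), but neither passed with an estimated correlation (adjusted p = 0.863 for each) or by exact permutation of scores (p = 0.0491 and 0.0403, adjusted p = 0.278 for each). These genes have close paralogs and pseudogenes that can share reads, so single members are uncertain. The scores of H3K27me3-high replicate 17 lay in the range of the low tumours. Without replicate 18 the calls of RPS29, RPL37A, HIST1H4K and HIST1H2AK ended, with log2 fold changes of -2.17, -1.89, -2.33 and -2.86. Without the 3 libraries that detect more genes, left out after seeing the data, 0 of 78 and 0 of 62 members were called, and the list medians were -1.38 and -1.17.

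Of 17 astrocyte genes, 2 were higher and 0 lower, and 5 were higher adjusted over the list alone, with a median log2 fold change of 1.15. The gap junction gene GJA1 stood at 1415 ± 870 against 145 ± 107 CPM (log2 3.29 ± 0.68, edgeR adjusted p = 0.0139). The folate enzyme gene ALDH1L1 stood at 838 ± 537 against 61.8 ± 73.6 CPM (log2 3.76 ± 0.92, adjusted p = 0.0284). The Wnt list had 2 of 20 members higher, WNT5B (log2 2.40 ± 0.59, adjusted p = 0.0297) and WNT5A (log2 2.03 ± 0.55, adjusted p = 0.0408), both ligands, and 6 adjusted over the list alone. The astrocyte and Wnt lists passed camera (adjusted p = 3.41e-05 and 0.00179), but not with an estimated correlation (adjusted p = 0.863 and 0.560) nor by exact permutation (p = 0.00513 and 0.00220, adjusted p = 0.0872 and 0.0747). Fry, which asks whether the genes of a list move one way, passed Wnt (adjusted p = 0.0275) and not the astrocyte list (0.0658). GJA1 lost its call without replicate 16 (adjusted p = 0.0508), ALDH1L1 without 16 or 18, and WNT5B without 15, 16 or 18. WNT5A lost its call in 9 of the 15 fits that left out a tumour, among them each of the 4 high tumours and 5 low tumours.

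Motile cilia genes, the signature of ependymal differentiation, gave no calls of single members: of 67 tested, 0 were called by edgeR, and 0 were called adjusted over the list alone. The lack of calls does not show equal levels. Camera placed the list higher in low tumours (adjusted p = 0.00179), while the median log2 fold change was -0.18, the mean 0.03 and the adjusted p with an estimated correlation 0.907, so the signs differ between summaries; the median turned to 0.19 with library totals as the only scaling. FOXJ1, the master regulator of motile ciliogenesis, stood at 233 ± 153 against 47.6 ± 33.6 CPM (log2 2.29 ± 0.95, adjusted p = 0.176), and the axonemal gene SPAG16 at 238 ± 154 against 831 ± 608 CPM (adjusted p = 0.0975). Without H3K27me3-high replicate 17, whose cilia score was -2.82 against 0.27 to 0.76 in the other high tumours, camera placed the list lower in low tumours (adjusted p = 0.00864) and 2 of 67 members were called lower. That share is below the 1978 of 17293 genes called lower in the same fit. The camera test used the preset correlation of 0.01, where the correlation estimated for this list over 15 tumours was 0.849, so the reversal is uncertain as well.

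**Figure D2:**
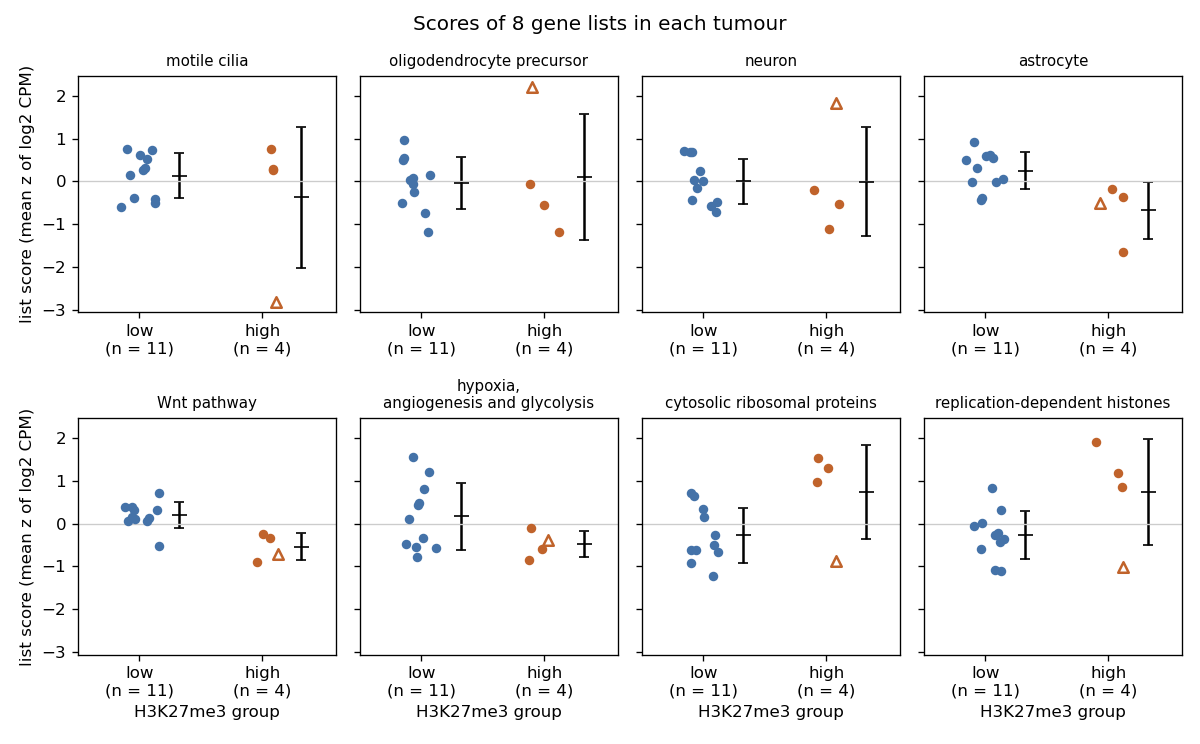
Score per tumour of 8 of the fixed gene lists, as the mean over members of log2 CPM standardised over 15 tumours, in H3K27me3-low (blue, n = 11) and H3K27me3-high tumours (orange, n = 4); the open triangle is H3K27me3-high replicate 17, and bars are mean and SD. Replicate 17 had the lowest cilia score, -2.82, and the highest oligodendrocyte precursor score, and it lay in the range of the low tumours for ribosomal proteins and histones.

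The extracellular matrix list (35 genes) and the list for hypoxia, angiogenesis and glycolysis (23 genes) were higher in low tumours by camera (adjusted p = 0.0214 and 0.00944), with 1 member (LAMA2) and 0 members called, and 0 in each adjusted over the list alone. Neither passed with an estimated correlation (adjusted p = 0.907 for each) or by exact permutation (p = 0.208 and 0.140, adjusted p = 0.442 for each). The hypoxia-induced genes BNIP3 and ANGPTL4 stood at 123.1 ± 60.8 against 49.0 ± 12.6 CPM and 43.7 ± 74.2 against 3.73 ± 1.961 CPM (adjusted p = 0.0712 and 0.119). The camera call of the matrix list ended without low replicates 3 or 7 or high replicates 15 or 16 (adjusted p up to 0.466), and that of the hypoxia list without low replicate 7 or high replicate 17 (adjusted p = 0.0579 and 0.0543).

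The other lists did not pass camera or the exact permutation, although single members did by edgeR. Among neural stem and radial glia genes (20 tested), FAM107A was higher (log2 2.499 ± 0.57, adjusted p = 0.0212), and PROM1 (log2 -1.50 ± 0.41, adjusted p = 0.0424) and FABP7, a radial glial lipid carrier (log2 -2.36 ± 0.65, adjusted p = 0.0449), were lower. Of 41 axon guidance genes, EPHA7 (log2 3.21 ± 0.60, adjusted p = 0.00849) and ROBO2 (log2 3.54 ± 0.73, adjusted p = 0.0136) were higher and EPHB4 lower (log2 -1.81 ± 0.43, adjusted p = 0.0264). ALX1, a homeobox transcription factor, was higher among 27 developmental transcription factors (log2 4.76 ± 0.83, adjusted p = 0.00699). The RNA-binding protein IGF2BP1 was higher at 18.4 ± 10.5 against 0.440 ± 0.799 CPM (log2 5.15 ± 0.91, adjusted p = 0.00735) among 9 oncofetal genes, in which the imprinted transcript H19 was lower (log2 -6.57 ± 1.68, adjusted p = 0.034). H19 turned to 1.30 without H3K27me3-high replicate 17 (adjusted p = 0.635). CLIC6 was higher among 10 choroid plexus genes (log2 3.95 ± 0.74, adjusted p = 0.00849), and ASPA, the aspartoacylase of oligodendrocytes, among 11 oligodendrocyte genes (log2 3.78 ± 0.93, adjusted p = 0.0300). EGFR among 15 receptor tyrosine kinases (log2 2.73 ± 0.77, adjusted p = 0.0497) and GLI3 among 11 Hedgehog genes (log2 2.25 ± 0.64, adjusted p = 0.0498) were just past the threshold. Adjusted over the list alone, 6 axon guidance genes were higher and 3 lower, 1 oligodendrocyte gene was higher and 1 lower, and the other lists of this paragraph and PRC1 kept the same counts. EPHA7, ROBO2, ALX1, IGF2BP1 and CLIC6 kept their calls in all 15 fits that left out a tumour. Without low replicates 1 and 5 and high replicate 18, left out after seeing the data, only IGF2BP1 of these genes kept its call. ROBO2 also lost its call with limma-voom and with the ribosomal protein share as a term, and its log2 fold change ranged from 1.23 to 3.88 over 29 alternatives. FAM107A, PROM1, FABP7, EPHB4, ASPA, EGFR and GLI3 lost theirs without replicate 18 and in other fits that left out a tumour.

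No member was called by edgeR over all genes in 16 further lists, nor among the cancer-testis antigens. The oligodendrocyte precursor list (8 genes) and the neuron list (15 genes) had medians of -3.78 and -2.19, set by H3K27me3-high replicate 17: SOX10 stood at 83.1 ± 166 CPM in the high group, LHFPL3 at 106 ± 194, GAD1 at 13.1 ± 19.99 and ELAVL4 at 12.1 ± 23.2. Without that tumour the medians were 2.06 and 1.91. Adjusted over the list alone, 6 precursor genes were lower, 2 cerebellar neuron genes higher and 1 cell cycle inhibitor higher, and 0 members passed in the other 13 lists. Medians were 1.26 for cerebellar neuron genes (6; ITPR1 and CALB1 had adjusted p = 0.0596 and 0.108), 0.24 for microglia and macrophages (22; CX3CR1 and CD163, 0.372 and 0.445), 0.73 for lymphocytes (11; CD8A and CD79B, 0.204 and 0.425) and 0.58 for interferon and MHC class I genes (23; GBP1 and HLA-B, 0.0906 and 0.398). They were 1.41 for NF-kB inflammation genes (25; CXCL1 and PTGS2, 0.113 and 0.134), 0.34 for endothelium (16; CLDN5 and ERG, 0.238 and 0.572), 0.34 for mural cells and fibroblasts (14; CNN1 and TAGLN, 0.313 and 0.351) and 0.50 for the cell cycle (34; MAD2L1 and MCM3, 0.0522 and 0.147). They were -0.10 for cell cycle inhibitors (7; CDKN1A and CDKN2A, 0.0751 and 0.264), -0.76 for HOX genes (14; HOXD3 and HOXB7, 0.290 and 0.441), 0.20 for the Notch pathway (16; NOTCH2 and DLL3, 0.206 and 0.211) and 0.89 for immediate-early and stress genes (15; DNAJB1 and ATF3, 0.197 and 0.294). The erythrocyte list (5; SLC4A1 and ALAS2, 0.404 and 0.534) and the mitochondrially encoded genes (13; MT-ND6 and MT-ND3, 0.490 and 0.775) had medians of 0.44 and 0.07. Replicate 17 moved other medians too: without it they were 2.38 for mitochondrially encoded genes, 1.34 for mural cells and fibroblasts, 1.13 for Notch, 0.97 for endothelium, 0.46 for cell cycle inhibitors, 0.28 for the cell cycle, 0.07 for erythrocytes and 0.03 for microglia and macrophages. Of the cancer-testis antigens, PRAME and TEX14 were tested, with log2 fold changes of 3.28 and 0.17 (adjusted p = 0.271 and 0.938).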

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

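The tests of H3K27me3-high replicate 17, the tests on that tumour as a held-out sample, the relation for the higher genes, the GC content test and the cell cycle test were chosen after the result was seen; the other tests here were set before it. Splits of the tumours were also counted, in 100 splits drawn into 4 and 11 tumours. Of these, 1 gave as many called genes as the study's groups, which is the study's own (866 genes, highest other 178). Likewise, 1 gave as many genes of at least 2-fold (844, highest other 178). Both counts thus exceeded every other split drawn, but not all possible splits were drawn. No other drawn split kept the high tumours other than replicate 17 together in the group of 4. Those tumours share a library make-up, so the splits cannot tell the H3K27me3 groups from that make-up. For the fixed lists, 92 of the 100 splits gave at least the 7 lists past camera (highest other 22), so chance cannot be excluded for the number of lists.

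In the high group, 15 of 152 values (named genes, list scores and library measures) had 1 tumour far from the other 3, where chance alone gives about 1 in 20. In 5 of the 15 the other 3 tumours had 0 reads, which fixes the outcome of this test. As a pooled count, the remaining 10 of 147 are near that chance rate. However, 9 of the 10 belong to replicate 17, so they are not spread over the high tumours. The values are also not independent of one another, so the pooled count is no test of chance. In that tumour GNG3 stood at 98.0 CPM (others 1.203 to 2.21), EED at 12.3 (62.0 to 67.4), EZH2 at 17.1 (79.4 to 104), FOXJ1 at 1.97 (43.6 to 78.0), UHRF2 at 30.7 (55.2 to 61.3), EGFR at 12.6 (23.9 to 25.9) and CDKN2A at 20.6 CPM (1.002 to 1.72). Its motile cilia score was -2.82 (0.27 to 0.76) and its ribosomal protein share 0.576% (5.37% to 5.68%). In replicate 18, HOXB7 stood at 12.1 CPM (0.184 to 0.247), NRK at 0.172 CPM and NPY2R, LINC00606 and LGALS9C at 0.0861 CPM each, where the other 3 high tumours had 0 reads; in replicate 15, LINC01697 stood at 0.200 CPM with 0 reads in the others.

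Replicate 17 as a whole lacked cilia genes and carried oligodendrocyte precursor and neuronal genes: against the median of the other 14 tumours, the median log2 ratio was -7.02 over 67 cilia genes, 6.87 over 8 precursor genes (PDGFRA at 1776 CPM, OLIG2 at 339) and 5.12 over 15 neuronal genes. Low depth is argued against, since 8 of the other 14 libraries had fewer reads. Adjacent brain tissue stays open: the precursor median exceeded the higher of the astrocyte and cerebellar neuron medians by 6.51 log2 units (largest interquartile spread 2.51), but the neuronal list rose with it, the oligodendrocyte list rose by 2.34, and the other tumours express astrocyte genes as well. An exchange with a low tumour is argued against, since its highest Spearman correlation with one was 0.802, below the 0.888 to 0.942 that low tumours reached among themselves, and each of the 11 low tumours was closest to another low tumour. Its highest correlation with a high tumour was lower still, 0.614, so a wrong label and a swap with a sample from outside the series stay open.

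The genes that separate the groups also followed the make-up of the libraries inside the low group. Across the 11 low tumours, the mean score of 687 genes lower in low tumours (ribosomal protein genes left out) rose with the log2 ribosomal protein share (Pearson r = 0.910, permutation p = 0.00024, Spearman rho = 0.909, p = 0.00023; r = 0.822 without the 2 tumours farthest in that share), and that of the 157 higher genes fell with it (r = -0.947, p = 3e-05, rho = -0.927, p = 0.0001; r = -0.900), adjusted p = 0.00036 and 9e-05 over 3 relations, where the central 95% of random gene sets gave r from -0.592 to 0.420 and from -0.728 to 0.639; in the 9 low tumours without replicates 1 and 5, r was 0.916 and -0.950. Replicate 17 had a ribosomal protein share like that of low tumours. For the 885 genes called higher without it, the median log2 difference was -0.415 (low mean minus replicate 17), against 1.64 for the other high tumours. That value met the prediction from library make-up. For the 1978 genes called lower it lay beyond the low tumours (0.707, against -1.80), which did not meet it. Replicate 17 also differed in its cilia, precursor and neuronal genes, so neither result can test the library axis. The lower genes were also shorter (median transcript length 3553 bases, where sets matched on expression gave a 5th percentile of 3692) and lower in GC content (median 45.28%, 5th percentile 46.5%, below all 10000 sets), so biases by length and GC content stay open. Among 264 other short genes, of up to 2194 bases, 3 were called higher and 25 lower, against 157 and 709 of all 16647. Their median log2 fold change was -0.38, against -1.72 for histone and ribosomal protein genes. They were not matched in length to the histone genes (median 488 bases), so this comparison cannot weigh against a length bias. RNA quality, library preparation and a tumour state that varies in both groups may each underlie this axis, and H3K27me3 level stays open as a biological explanation, because the groups and the axis are confounded in 3 of the 4 high tumours.

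EZH2, SUZ12, EED and AEBP2 were lower in the low tumours while EZHIP was higher. Lower proliferation as the whole cause is argued against, since the cell cycle list had a median log2 fold change of 0.503 (interquartile range -0.06 to 0.85) where the 4 genes had -1.42, although MAD2L1 of that list (-2.31, adjusted p = 0.0522) and the histone genes, made in S phase (median -1.93, 25 of 63 lower), point the other way. The histone share was itself part of the library make-up of H3K27me3-high replicates 15, 16 and 18. The histone genes therefore cannot tell proliferation from that make-up. The library axis cannot be told apart from the groups for these 4 genes: within the 11 low tumours their mean score had r = 0.713 with the ribosomal protein share (permutation p = 0.0150, adjusted p = 0.0150, rho = 0.755, p = 0.01004), but r fell to 0.346 without the 2 farthest tumours, and the central 95% of random sets of 4 genes reached up to 0.790. In the 9 low tumours without replicates 1 and 5, r was 0.715 (permutation p = 0.0365). The prediction set beforehand, r of at least 0.5 with p under 0.05, was met; the demand that r exceed random sets was added after the value was seen, so by the first rule alone the library axis fits. With that share as a term, chosen after seeing the data, all 4 lost their calls as their folds shrank (EZH2 -0.40 ± 0.35 SE, SUZ12 -0.48 ± 0.31, EED -0.64 ± 0.42, AEBP2 -0.93 ± 0.36; adjusted p from 0.203 to 0.614), while EZHIP kept its call (3.41 ± 0.76, 0.0407); without replicate 17 as well, folds were -0.90 ± 0.50, -1.07 ± 0.43, -1.61 ± 0.44, -1.76 ± 0.43 and 3.13 ± 1.05 (adjusted p from 0.129 to 0.435), against -1.81 ± 0.34, -1.83 ± 0.29, -1.70 ± 0.26, -2.77 ± 0.32 and 5.23 ± 1.03 without that tumour and without the term.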

How the results depend on the processing

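The settings chosen after seeing the data are named here as added. Without one tumour at a time, higher genes ranged from 33 to 885, lower genes from 100 to 1978, genes of at least 2-fold from 133 to 2707, lists past camera from 5 to 12 and lists past the permutation from 0 to 2. Higher, lower and 2-fold genes were 560, 1266 and 1648 with DESeq2; 46, 91 and 137 with limma-voom; 1034, 1920 and 2593 with sample weights; and 62, 387 and 449 with no low-count filter, which tests 41709 genes. Library totals alone gave 249 lower and 414 2-fold genes, with 2 lists past the permutation. One surrogate variable gave 379 higher genes, and an adjusted p under 0.01 gave 20 higher and 125 lower. Camera with an estimated correlation passed 0 lists and fry 1. Among added settings, the 3 libraries (low 1, low 5, high 18) as a term gave 104, 409 and 508, the ribosomal protein share as a term 62, 181 and 240, and that share without high 17 gave 6, 6 and 12. Without the 3 libraries there were 3, 1 and 4 genes with 12 lists past camera, and without those and high 17 there were 273, 825 and 1098 genes with 13 lists. The cause was not tested.

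H19 reversed to 1.30 without high 17, the highest of a range from -7.59 without one tumour at a time, and to 4.48 without the 3 libraries and high 17. Motile cilia reversed in camera in the same settings (adjusted p = 0.00864 and 0.00467; without one tumour at a time, from 6.82e-11 to 0.00993). Microglia and macrophages passed in the other direction in the second (adjusted p = 0.0291). EGFR and GLI3 turned to -0.92 and -0.34 without high 17 and with the share as a term. The 53 called named genes were tested in 27 to 29 alternatives each and the 7 lists past camera in 22; apart from the cases above, they kept their direction there. Of the lower genes tested, 682 of 709 kept their sign without high 17, 682 of 706 without the 3 libraries and high 17, 692 of 709 with sample weights, 697 with the share as a term and without high 17 (154 of 157 higher genes), 703 with the share as a term, 707 without high 15 and 708 with limma-voom; in the other settings all did. Of 53 called named genes, 12 kept their calls without each tumour in turn. ANGPTL1 kept its call in all 29 alternatives, with adjusted p from 2.62e-18 to 0.0344. No paired analysis was possible because the groups share no replicate numbers. Depth limits genes with few reads in the high libraries, such as NRK and NPY2R.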

Other observations

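The tests on cilia scores were chosen after the result was seen; the chromosome test was set before it. Some genes called in the fit without H3K27me3-high replicate 17, an alternative set before the data were examined, are named here after their values were seen. CRIP1, a small LIM-domain protein, stood at 7.66 ± 8.43 CPM in low tumours (SD, n = 11) against 1210 ± 546 CPM in the other 3 high tumours, a log2 fold change of -7.31 ± 0.64 (edgeR adjusted p = 1.53e-05), with 3.68 CPM in replicate 17. With all 15 tumours it was also lower in low tumours, at -6.82 (adjusted p = 0.00268). ALDH1L1-AS2, which overlaps the astrocyte gene ALDH1L1, stood at 26.4 ± 10.7 against 0.369 ± 0.359 CPM (log2 5.95 ± 0.71, adjusted p = 9.38e-05), and the transcription factor inhibitor MDFI at 18.8 ± 12.5 against 0.369 ± 0.359 CPM (log2 5.47 ± 0.94, adjusted p = 0.00127); both stood near the low tumours in replicate 17, at 20.04 and 20.9 CPM, and with all 15 tumours neither was called (2.28, adjusted p = 0.177, and 1.73, adjusted p = 0.355). The strand setting is not stated, so the value of ALDH1L1-AS2 is uncertain and can hold reads of ALDH1L1, which stood at 838 CPM in low tumours and 167 CPM in replicate 17. In the same fit 4 of 35 matrix genes, 4 of 17 astrocyte genes and 3 of 16 receptor tyrosine kinases were higher and none of them lower, and 59 of 78 ribosomal protein genes and 48 of 65 histone genes were lower.

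Low tumours differed among themselves in cilia expression. Across the 11, the motile cilia score fell with the scores for hypoxia, angiogenesis and glycolysis (Pearson r = -0.651, permutation p = 0.0340; Spearman rho = -0.464, p = 0.155), extracellular matrix (r = -0.645, p = 0.0292; rho = -0.545, p = 0.0867), microglia and macrophages (r = -0.672, p = 0.0213; rho = -0.609, p = 0.0521) and NF-kB inflammation (r = -0.685, p = 0.0238; rho = -0.482, p = 0.137), but not with the cell cycle (r = -0.021, p = 0.950; rank p = 0.775). Adjusted over the 5 relations, p was 0.0425 for the first 4 and 0.950 for the cell cycle, and no Spearman p was under 0.05. Without the 2 tumours farthest in cilia score r was -0.549, -0.799, -0.860, -0.764 and 0.054, and in the 9 tumours without low replicates 1 and 5 it was -0.712, -0.893, -0.717, -0.827 and -0.187. The hypothesis that low-H3K27me3 tumours range from ciliated to hypoxic and inflamed states is consistent with the r of -0.651 for hypoxia, but the rank correlations leave it open.

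Whole-chromosome expression was compared as a hypothesis on gene dosage, from trimmed means over genes of each autosome. None of 22 autosomes passed after adjustment, a count of 0 by exact permutation with 5 at an unadjusted p under 0.05; the smallest p was 0.00659 for chromosome 12 (859 genes, low -0.06 ± 0.10 and high 0.21 ± 0.22 log2 units, adjusted p = 0.137).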
